A study of Mus musculus with 51 samples.

How the data were processed

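Gene expression was measured on 51 Affymetrix mouse arrays, each hybridised with biotin-labelled cRNA from 1 single oocyte or embryo. Per the labels, total RNA was taken from each cell or embryo with a micro-scale column kit and amplified over 2 rounds of cRNA synthesis. The authors made the values with RMA, with no version given. The deposited table holds log2 values for 45101 probe sets. The base of the logarithm is not stated in the file and was taken from the values: 1 probe set spanned 13.8 units over the arrays, more than the 11.1 units that the full range of a 16-bit scanner spans in natural logarithms. The deposited log2 values had been centred for each probe set, a step the labels do not mention. In 94.3% of the probe sets exactly 1 array was at 0, and in these 24 to 26 of the 51 arrays lay below 0. A value is thus a difference from a baseline of its own probe set and carries no absolute level, and only differences between arrays are reported. Arrays have no read depth, so the number of embryos and the spread between them limit the precision. Detection calls were not used here, so signal over background was not judged.

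Of the 45101 probe sets, 64 were manufacturer controls, 34958 had exactly 1 gene symbol, 932 had several and 9211 had none. Probe sets with several symbols name no gene, so Zscan4d and H19 have no value of their own. For each of 18194 genes, the probe set with the largest SD over all 51 arrays was used. The rule written before the data were examined took the probe set with the highest mean, and a filter planned with it removed the lowest 30% of genes by mean. Means of centred values hold no level, so the SD took the place of the mean in both after the values had been seen. Of these genes 9012 had more than 1 probe set, and for 14240 of the 18194 both rules gave the same one. Gene positions are from the GRCm38.p6 assembly (RefSeq), joined by gene identifier, and 617 genes were X-linked.

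The design has 13 groups: 3 metaphase II (MII) oocytes, and at each of 6 stages 3 embryos made by in vitro fertilisation (IVF) and 5 embryos cloned by transfer of a Sertoli cell nucleus. The comparisons, their tests, the gene lists and the rule for naming genes were set before the data were examined. Clones were compared with IVF embryos at each stage using only the 8 arrays of that stage. Stage-to-stage changes were tested in a fit of the 21 oocyte and IVF arrays and, apart from it, in a fit of the 30 clone arrays. The difference between a clone transition and the IVF transition was tested as an interaction in 1 fit of all 51 arrays. These 22 comparisons used limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with p-values adjusted by the method of Benjamini and Hochberg over 18194 genes and a threshold of 0.05. No filter and no further normalization were applied. Differences are on the log2 scale and are given as the estimate ± its standard error from limma. Replicate numbers count single embryos. The correlation of residuals between clones and IVF embryos of the same number lay between -0.204 and 0.102, so replicates were not treated as pairs.

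The genes named for a stage are the 8 largest rises and the 8 largest falls among genes past the threshold whose clone and IVF values did not overlap. Y-linked genes and symbols that are only clone or locus numbers were left out. For IVF transitions 5 rises and 5 falls are named, and for clone transitions and differences of transitions 3 of each. Xist, Pou5f1, Nanog, Sox2, Cdx2, Gata6, Dppa3, Dnmt1, Dnmt3b and Sox9 were followed in every comparison. From each list up to 4 members with the smallest adjusted p are named.

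Shifts of 24 gene lists were tested with camera (limma) at its preset correlation of 0.01, adjusted over the lists and the stages or transitions of 1 series. The lists were written from general knowledge, none was chosen on these samples, and they hold maternal oocyte factors, zygotic activation and 2-cell genes, nucleolar ribosome biogenesis factors, pluripotency and inner cell mass, trophectoderm, primitive endoderm, epithelial junction and cavitation, Sertoli cell, other testis somatic cells, cumulus cell, sperm and late germ cell, imprinted genes, genes with H3K27me3-type imprinting, the Xist region with the Magea and Xlr families, chromatin and DNA methylation regulators, p53 and cell death, heat shock and unfolded protein stress, glycolysis, DNA replication and G1-S, mitosis and spindle, ribosomal proteins, the mitochondrial respiratory chain, the proteasome, and all X-linked genes. Camera with an estimated correlation and fry were run beside it. In each comparison the members of a list were also adjusted over the list alone.

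The spread between embryos is the root mean square over genes of an embryo's deviation from its group mean, scaled for the group size. Array quality was taken from a pair of measures: the log2 difference of the 3′ and 5′ control probe sets, averaged over Actb and Gapdh, and the mean of the bacterial hybridisation controls that are added with each labelled sample. The position of an embryo in development is its projection on the line from the mean of the IVF stage before to the mean of the IVF stage after, where 0 is the earlier and 1 the later. For blastocysts the line ran from IVF morulae to IVF blastocysts, each IVF blastocyst being placed on a line made without it. The X-linked offset of an embryo is its mean over X-linked genes minus its mean over the other genes. These values were compared with exact two-sided permutation tests of 5 clones against 3 IVF embryos, which have 56 splits and a smallest p of 0.0357, adjusted over the 6 stages. They were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

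The pipeline was tested on simulated data with 200 changed genes at the sample sizes and spreads of each comparison. For clones against IVF embryos it recovered 37.3% to 55.2% of changes of log2 1. It recovered 58.2% to 80.6% of those of log2 2 and 74.2% to 98.5% of log2 4. Of 123 to 166 calls 7 to 13 were false. With no change it called 0 genes at 5 stages and 1 in blastocysts. Other splits of the real 1-cell arrays gave up to 178. Alternatives were: 1 fit of all 51 arrays, a 2-fold minimum, the mean of all probe sets of a gene, centring of each array on its median, quantile normalization of a stage again, the replicate number as a block, array weights, the 3′/5′ difference as a covariate, Actb or Gapdh alone, leaving out each embryo in turn, and the other list tests. Added after the data had been seen were the probe set with the highest mean, a filter on the lowest 30% by SD, and the Y-linked gene Eif2s3y or the hybridisation controls as a covariate. All deposited arrays were used, without scan images or raw intensities.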

Results

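The data were log2 expression values of 18194 genes in 51 single mouse oocytes and embryos, 1 array for each. There were 3 MII oocytes, and 3 IVF and 5 cloned embryos at each of 6 stages, the 1-cell, 2-cell, 4-cell and 8-cell stages, the morula and the blastocyst. They were collected 16, 32, 48, 62, 72 and 84 hours after sperm addition or activation. Clones were made by placing the nucleus of a Sertoli cell, the somatic support cell of the testis, into an oocyte, so donor nuclei were male. Per the labels, oocytes and IVF embryos were of the B6D2F1 strain and donor nuclei of the B6CBF1 strain. All values are relative to a baseline of their own probe set, and n is 5 clones and 3 IVF embryos at each stage unless another number is given. The series asks how gene expression of cloned embryos differs from that of fertilised embryos through preimplantation development.

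At the 1-cell stage the deubiquitinase gene Usp17la (chromosome 7, 104857016 to 104862667, GRCm38.p6) was lower in clones than in IVF embryos by -7.76 ± 0.38 on the log2 scale (adjusted p = 0.00137), with means of -0.46 ± 0.01 in clones and 7.30 ± 0.93 in IVF embryos (SD). Cpne1, which encodes a calcium-dependent membrane-binding protein (chromosome 2, 156071841 to 156111965), was higher by 6.34 ± 0.47 (adjusted p = 0.00234). Other genes higher in clones were Mfsd4b4 by 5.42 ± 0.37, the proline transporter gene Slc6a20a by 4.91 ± 0.41, Lratd1 by 4.63 ± 0.55, Tmem109 by 4.51 ± 0.34 and the endoplasmic reticulum ubiquitin ligase gene Syvn1 by 4.38 ± 0.50. So were the Mediator subunit gene Med20 by 4.38 ± 0.68 and the peroxidase gene Pxdn by 4.28 ± 0.39. Lower in clones were the splicing factor gene Cdc5l at -5.31 ± 0.44, the actin regulator gene Wasf3 at -4.51 ± 0.56 and the endosomal sorting gene Snx6 at -4.28 ± 0.72. Further falls were those of the transcriptional inhibitor gene Id2 at -4.22 ± 0.63, Dcdc2c at -3.74 ± 0.57, the ectonucleotidase gene Entpd1 at -3.25 ± 0.61 and the meiotic kinetochore gene Meikin at -3.16 ± 0.46. Their adjusted p lay between 0.00174 and 0.0295, and in Med20 and Dcdc2c 1 clone lay apart from the other 4. In all, 640 genes were higher and 508 lower in clones at the 1-cell stage, of which 502 and 414 by at least 2-fold.

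Zygotic activation and 2-cell genes, which are first transcribed around the 1- and 2-cell stages, were the only list to shift at the 1-cell stage. Of 20 members 4 fell and 1 rose, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.00503). The adjusted p was 0.218 with an estimated correlation. Beside Usp17la, the list included the early embryo genes Dppa4 at -1.89 ± 0.17, Pramel7 at -2.27 ± 0.29 and Dppa2 at -2.05 ± 0.28. Single members of other lists passed the test at this stage. Among them were Trim28, a corepressor that guards imprints, higher by 3.17 ± 0.34, the spindle checkpoint gene Bub1b, higher by 3.82 ± 0.35, and separase (Espl1), higher by 1.60 ± 0.08. Hybridisation controls were lower on the clone arrays by -0.98 (exact p = 0.0357, adjusted 0.0536), and with them as a covariate 521 genes passed. The clone arrays lay apart from one another, with replicates 1 to 3 between -0.948 and -0.638 and replicates 4 and 5 at 0.371 and 0.477, against 0.541 to 0.748 in IVF embryos. The 3′/5′ difference of Actb was -2.45 and -1.69 in replicates 4 and 5 and between -0.016 and 0.413 in the others. With another probe set of the gene, Snx6 was 1.23 higher in clones (adjusted p = 0.179).

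At the 2-cell stage D1Pas1, a testis gene for an RNA helicase (chromosome 1, 186967416 to 186970627), was lower in clones by -6.07 ± 0.30, and the X-linked gene Fmr1nb (chromosome X, 68761839 to 68804561) by -5.49 ± 0.28 (adjusted p = 0.000756 for both). Ndrg1, a stress-responsive gene (chromosome 15, 66929318 to 66969641), was higher by 5.44 ± 0.62 (adjusted p = 0.0135). Clones also had more of the lysosomal protease gene Ctss (4.72 ± 0.36), Pde6a (4.54 ± 0.62) and the small GTPase gene Rab29 (4.11 ± 0.73). The same held for the mitochondrial fusion gene Miga1 (4.01 ± 0.61), Pus7l (3.98 ± 0.70), Rnf157 (3.97 ± 0.39) and the receptor adaptor gene Gab1 (3.61 ± 0.52). They had less of the synaptonemal complex gene Sycp1 (-4.72 ± 0.79), the nucleolar gene Nolc1 (-4.50 ± 0.81) and the X-linked receptor gene Gpr50 (-4.47 ± 0.39). Syt11 (-4.47 ± 0.09, adjusted p = 2.21e-05), the keratin gene Krt28 (-4.43 ± 0.53) and the RNA-binding protein gene Tial1 (-4.36 ± 0.23) were lower as well. In Gpr50 and Tial1 1 clone lay apart from the other 4. At this stage 92 genes were higher and 339 lower in clones, 71 and 305 of them by at least 2-fold.

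Nucleolar ribosome biogenesis factors shifted down in 2-cell clones. Of 30 members 5 fell, or 12 with 1 rise adjusted over the list alone (camera adjusted p = 3.78e-07), and the adjusted p was 0.418 with an estimated correlation. The members with the smallest p were the pre-ribosome factors Bop1 at -2.39 ± 0.32, Nop2 at -1.86 ± 0.26, Rrp9 at -2.37 ± 0.36 and Wdr12 at -1.76 ± 0.28. Among zygotic activation and 2-cell genes, Rfpl4b at -2.74 ± 0.42 and Klf17 at -0.93 ± 0.16 fell, or 5 with 1 rise adjusted over the list alone (camera adjusted p = 0.000984, and adjusted p = 0.218 with an estimated correlation). Chromatin and DNA methylation regulators shifted down as well, with 2 of 36 falling, Trim28 at -1.81 ± 0.05 and the histone methyltransferase gene Setdb1 at -1.21 ± 0.14, or 3 adjusted over the list alone (camera adjusted p = 0.00166, and adjusted p = 0.218 with an estimated correlation). Genes with H3K27me3-type imprinting, silenced on the maternal allele by a histone mark, shifted up. Gab1 and the transcription factor gene Etv6 (2.92 ± 0.47) were the 2 of 14 that rose, or 3 adjusted over the list alone (camera adjusted p = 0.0209, and adjusted p = 0.332 with an estimated correlation). Maternal oocyte factors had 0 of 26 members past the threshold, by either adjustment, and a downward shift of the list (camera adjusted p = 0.0463, and adjusted p = 0.845 with an estimated correlation). That call ended when each array was centred on its median (adjusted p = 0.0501). The hybridisation controls were 1.24 higher on the clone arrays (exact p = 0.0357, adjusted 0.0536). With them as a covariate limma called 0 genes at the 2-cell stage, with 890 at an unadjusted p under 0.05, and 2 of the 5 list calls were kept. After quantile normalization of the stage again, 127 genes were higher and 164 lower, and with the other probe set Nolc1 was 0.41 higher (adjusted p = 0.285).

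At the 4-cell stage Rpl39l, a ribosomal protein gene best known from testis (chromosome 16, 10170197 to 10174911), was lower in clones by -8.50 ± 0.53 (adjusted p = 0.00204). The pluripotency gene Pou5f1 (chromosome 17, 35506032 to 35510777) was lower by -2.09 ± 0.12 (adjusted p = 0.00195), with means of -2.11 ± 0.20 in clones and -0.01 ± 0.11 in IVF embryos (SD). Higher in clones were the microtubule-associated gene Nav1 (4.57 ± 0.63), the lipid droplet gene Plin2 (3.64 ± 0.61), the small GTPase gene Cdc42 (3.54 ± 0.65) and Fez1 (3.51 ± 0.50). Higher too were Arhgef18 (3.28 ± 0.43), Atp10d (3.22 ± 0.47), the cell death gene Pawr (3.18 ± 0.25) and Ssr1 (3.09 ± 0.57). Lower in clones were the X-linked genes Mageb16 (-5.76 ± 0.63; chromosome X, 79623231 to 79671435), Fmr1nb (-5.55 ± 0.60) and Lonrf3 (-4.59 ± 0.38). The ketone body enzyme gene Oxct1 (-4.70 ± 0.74), the Wnt receptor gene Fzd4 (-4.54 ± 0.28), the zinc transporter gene Slc39a2 (-4.24 ± 0.14) and the 2-cell gene Tcstv3 (-4.23 ± 0.47) were lower too. In Mageb16, Fmr1nb and Fzd4 the clone of replicate 2 lay apart from the other clones, as did that of replicate 5 in Fez1. In total 84 genes were higher and 328 lower, 66 and 276 of them by at least 2-fold.

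Among 21 genes of pluripotency and the inner cell mass, 3 fell at the 4-cell stage, Pou5f1, Klf2 (-1.90 ± 0.21) and Esrrb (-2.05 ± 0.37), and the count was the same adjusted over the list alone (camera adjusted p = 0.00503, and adjusted p = 0.409 with an estimated correlation). Zygotic activation and 2-cell genes again shifted down, with Tcstv1 (-4.19 ± 0.32), Tcstv3 and Tdpoz1 (-3.71 ± 0.51) falling, or 6 with 1 rise adjusted over the list alone (camera adjusted p = 0.000662, and adjusted p = 0.218 with an estimated correlation). Of 30 nucleolar ribosome biogenesis factors, Wdr12 (-2.37 ± 0.23), Bop1 (-2.27 ± 0.25) and Nhp2 (-0.72 ± 0.08) fell and Gar1 (0.78 ± 0.11) rose, or 8 and 1 adjusted over the list alone (camera adjusted p = 2.04e-05, and adjusted p = 0.218 with an estimated correlation). Trim28 (-1.32 ± 0.09) and the polycomb gene Ezh2 (-1.87 ± 0.17) were the 2 of 36 chromatin regulators that fell, or 4 with 1 rise adjusted over the list alone (camera adjusted p = 0.00371, and adjusted p = 0.383 with an estimated correlation). Of 26 maternal factors the oocyte gene Padi6 (-1.52 ± 0.23) fell, by either adjustment (camera adjusted p = 0.0044, and adjusted p = 0.579 with an estimated correlation). Of 23 mitosis genes the survivin gene Birc5 (-0.73 ± 0.12) fell, or 5 adjusted over the list alone (camera adjusted p = 0.00521, and adjusted p = 0.579 with an estimated correlation). That call ended after quantile normalization (adjusted p = 0.085). Genes with H3K27me3-type imprinting shifted up, with Jade1 (2.81 ± 0.51) the 1 of 14 that rose, or 4 adjusted over the list alone (camera adjusted p = 0.00318, and adjusted p = 0.418 with an estimated correlation). Of 20 p53 and cell death genes 0 passed by either adjustment, with an upward shift of the list (camera adjusted p = 0.0493, and adjusted p = 0.594 with an estimated correlation). The p53 target Ccng1 stood at 2.58 ± 1.00. Hybridisation controls were 1.26 higher on the clone arrays of this stage (exact p = 0.0357, adjusted 0.0536). With them as a covariate limma called 0 genes, with 1701 at an unadjusted p under 0.05, and Plin2 stood at -0.78. Of the 8 list calls at this stage 0 were kept with them. Quantile normalization again gave 118 higher and 179 lower.

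At the 8-cell stage the collagen triple helix gene Cthrc1 (chromosome 15, 39076932 to 39087121) was lower in clones by -6.74 ± 1.26 (adjusted p = 0.033), although the clone of replicate 4 stood at 5.02 and the others between -0.16 and 0.38. The developmental transcription factor gene Pax6 was lower by -5.82 ± 0.12 (adjusted p = 1.68e-05). Mbnl2, a splicing regulator gene with H3K27me3-type imprinting (chromosome 14, 120275652 to 120431698), was higher by 5.60 ± 0.92 (adjusted p = 0.0231). Clones also exceeded IVF embryos in the annexin gene Anxa2 (5.22 ± 1.01), the basement membrane collagen gene Col4a1 (5.04 ± 1.06) and Niban2 (4.82 ± 0.89). They did so in Akr1b8 (4.75 ± 0.98), Etl4 (4.45 ± 0.72), Ccng1 (4.04 ± 0.88) and the efflux transporter gene Abcg2 (4.04 ± 0.43). They fell below in Borcs6 (-5.97 ± 0.35), the 2-cell gene Zfp352 (-5.85 ± 0.80), Tmem30b (-5.67 ± 0.69), Klhl8 (-5.52 ± 0.69), the X-linked transketolase-like gene Tktl1 (-5.32 ± 1.06) and the cytokine signalling gene Socs2 (-5.27 ± 0.24). The clone of replicate 4 also lay apart from the other clones in Etl4 and Klhl8, that of replicate 2 in Borcs6 and that of replicate 3 in Sox2. The label of the clone of replicate 4 was in doubt, since its Y-linked Eif2s3y lay at -5.25, near the oocytes, although donors were male. The embryo was kept. At this stage 391 genes were higher and 813 lower, 120 and 747 of them by at least 2-fold, and 237 and 792 with each array centred on its median. Without the clone of replicate 4 these were 223 and 654, Cthrc1 stood at -7.73, and Col4a1, Niban2, Akr1b8 and Ccng1 no longer passed (adjusted p = 0.0546, 0.0515, 0.0688 and 0.0667).

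Pluripotency genes were lower in 8-cell clones. Of 21 members 6 fell, by either adjustment, with 1 rise adjusted over the list alone. Among them were Klf2 (-2.26 ± 0.28), Sox2 (-1.33 ± 0.17), Esrrb (-3.61 ± 0.57) and Tdgf1 (-2.77 ± 0.53), and Pou5f1 was lower by -0.88 ± 0.18 (adjusted p = 0.0418, and 0.0736 without the clone of replicate 4). The list had a camera adjusted p of 0.0493, an adjusted p = 0.579 with an estimated correlation, 0.151 with each array centred on its median, 0.207 after quantile normalization and 0.143 with the clones of replicate 4 left out. Maternal oocyte factors shifted down with 4 of 26 falling, Zp3 (-2.75 ± 0.33), Bmp15 (-0.88 ± 0.14), Btg4 (-2.03 ± 0.35) and Gdf9 (-2.88 ± 0.59), or 9 adjusted over the list alone (camera adjusted p = 0.000662, and adjusted p = 0.218 with an estimated correlation). Of the 20 zygotic activation and 2-cell genes 5 fell, among them Tcstv1 (-4.21 ± 0.53), Zfp352, Tcstv3 (-4.04 ± 0.72) and Sp110 (-3.36 ± 0.72), or 6 with 1 rise adjusted over the list alone (camera adjusted p = 0.00296, and adjusted p = 0.418 with an estimated correlation). Nucleolar ribosome biogenesis factors had 4 falls, Wdr12 (-2.52 ± 0.16), Ebna1bp2 (-1.44 ± 0.14), Bop1 (-2.27 ± 0.36) and Utp14a (-1.47 ± 0.29), or 8 with 1 rise adjusted over the list alone (camera adjusted p = 3.29e-05, and adjusted p = 0.218 with an estimated correlation). Of 23 mitosis genes Espl1 (-1.16 ± 0.11), cyclin A2 (Ccna2, -1.30 ± 0.23) and Ttk (-2.13 ± 0.41) fell, or 5 adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.431 with an estimated correlation). Chromatin regulators had 3 falls, with Trim28 (-1.68 ± 0.25), Prdm9 (-2.07 ± 0.38) and Kdm1a (-2.26 ± 0.42), and 2 rises, with the DNA demethylase gene Tet2 (2.78 ± 0.46), or 7 and 2 adjusted over the list alone. Their camera adjusted p was 0.0132, with adjusted p = 0.431 with an estimated correlation, 0.0516 with arrays centred on their medians and 0.126 after quantile normalization. Markers of cumulus cells, the follicle cells that surround the oocyte, shifted up with follistatin (Fst, 0.27 ± 0.05) the 1 of 17 that rose, by either adjustment (camera adjusted p = 0.00885, and adjusted p = 0.418 with an estimated correlation). Markers of sperm and late germ cells shifted up with 0 of 17 past the threshold (camera adjusted p = 0.0226, adjusted p = 0.583 with an estimated correlation and 0.102 after quantile normalization). Camera ranks a list against the other genes, and the mean difference over all genes was -0.207 at this stage. The calls for cumulus and germ cell markers thus give a place above other genes and not by themselves a rise of such RNA. Hybridisation controls were 0.826 higher on the clone arrays (exact p = 0.0357, adjusted 0.0536). With them as a covariate 15 genes passed and 1 of the 8 list calls was kept. Quantile normalization again gave 486 higher and 524 lower. Socs2 stood at 0.06 with the other probe set (adjusted p = 0.128).

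**Figure D1:**
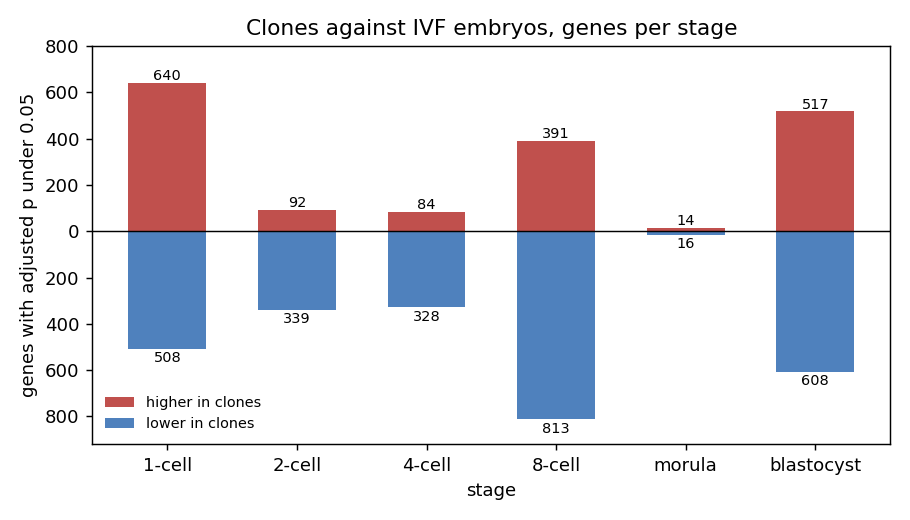
Genes higher (above 0) and lower (below 0) in clones than in IVF embryos at each stage, adjusted p under 0.05, in 5 clones and 3 IVF embryos. Lower genes outnumbered higher ones at the 2-cell (339 and 92), 4-cell (328 and 84) and 8-cell stages (813 and 391), with smaller excesses of 164 over 127, 179 over 118 and 524 over 486 after quantile normalization again.

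At the morula stage the X-linked homeobox gene Rhox5, expressed in Sertoli cells and placenta (chromosome X, 37754608 to 37808878), was higher in clones by 8.07 ± 0.38 (adjusted p = 0.000823), with means of 7.75 ± 0.64 in clones and -0.32 ± 0.28 in IVF embryos (SD). Ly6e, a cell surface protein gene, was higher by 7.10 ± 0.23 (adjusted p = 0.000181). The actin methyltransferase gene Setd3 (3.78 ± 0.38), Trim2 (3.73 ± 0.38), the immediate early gene Fos (3.56 ± 0.36), the SNARE gene Gosr2 (2.47 ± 0.28), the phenylalanine tRNA synthetase gene Farsb (2.30 ± 0.20) and Nudt9 (1.75 ± 0.19) were also higher. Lower were Cthrc1 (-5.85 ± 0.53), Rab38 (-5.66 ± 0.26), the X-linked genes Mageb16 (-5.41 ± 0.46), Rps6ka6 (-4.43 ± 0.32) and Dmd (-3.45 ± 0.37). The class I histocompatibility gene H2-K1 (-5.40 ± 0.52), whose sequence differs between mouse strains, Mpped2 (-3.14 ± 0.10) and the homeobox gene Pitx1 (-3.09 ± 0.15) were lower too. The pluripotency gene Sox2 differed by -5.13 ± 0.82 (adjusted p = 0.0783), with means of -1.06 ± 0.92 in clones and 4.08 ± 1.59 in IVF embryos (SD). In all, 14 genes were higher and 16 lower, 10 and 15 by at least 2-fold, with 1820 genes at an unadjusted p under 0.05. The count was 65 without the clone of replicate 4, which lay apart from the other clones in Fos, H2-K1 and Rps6ka6, and 6 without that of replicate 3.

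Of 79 respiratory chain genes 0 passed over all genes and 9 rose adjusted over the list alone (camera adjusted p = 0.000185, and adjusted p = 0.45 with an estimated correlation), with Ndufs8 at 0.30 ± 0.05 and Ndufb3 at 0.65 ± 0.11 (adjusted p = 0.0963 over all genes for both). Chromatin regulators shifted down, with the histone deacetylase gene Hdac3 (-0.82 ± 0.09) the 1 of 36 that fell, or 2 adjusted over the list alone (camera adjusted p = 0.000662, and adjusted p = 0.418 with an estimated correlation). Pluripotency genes shifted down with 0 of 21 past the threshold, or 1 fall adjusted over the list alone (camera adjusted p = 0.0253, and adjusted p = 0.719 with an estimated correlation). Genes with H3K27me3-type imprinting shifted up with 0 of 14 past the threshold by either adjustment (camera adjusted p = 0.0226, and adjusted p = 0.594 with an estimated correlation), Mbnl2 standing at 4.69 ± 1.36 and Gab1 at 1.57 ± 0.42. Among nucleolar ribosome biogenesis factors 0 of 30 passed, or 1 rise adjusted over the list alone (camera adjusted p = 0.0459 for a downward shift, adjusted p = 0.845 with an estimated correlation, 0.0931 with arrays centred on their medians and 0.103 after quantile normalization). X-linked genes shifted down, with 4 of 617 lower and 1 higher, or 35 and 3 adjusted over the list alone (camera adjusted p = 0.00173, and adjusted p = 0.845 with an estimated correlation). Their mean was -0.38 and their median 0.00574, so mean and median differed in sign. That call ended with Eif2s3y as a covariate, where the mean was -0.237 (adjusted p = 0.217). Of the 6 list calls in morulae 2 were kept with Eif2s3y and 3 with the hybridisation controls as a covariate. Quantile normalization again gave 8 higher and 15 lower genes, and Gosr2 stood at -0.33 with the other probe set (adjusted p = 0.834).

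At the blastocyst stage Magea5, an X-linked gene of the MAGE family (chromosome X, 155053061 to 155063151), was lower in clones by -7.08 ± 0.82 (adjusted p = 0.00908). App, the amyloid precursor protein gene (chromosome 16, 84952666 to 85175255), was higher by 5.78 ± 0.42 (adjusted p = 0.00297). Higher in clones were also genes of the cell surface and matrix, Cd47 (5.13 ± 0.31), Cd81 (4.64 ± 0.56), Alcam (4.63 ± 0.29) and Timp3 (4.17 ± 0.41). So were the actin-binding gene Cald1 (5.08 ± 0.81), the transcription coactivator gene Cited2 (4.30 ± 0.52) and the sterol synthesis gene Cyp51 (4.23 ± 0.42). Lower were the germ cell gene Asz1 (-5.61 ± 0.19, adjusted p = 0.000131), Msc (-4.93 ± 0.89) and the X-linked genes Rps6ka6 (-4.34 ± 0.57), Mageb16 (-4.30 ± 0.72), Fmr1nb (-4.28 ± 0.88), Tktl1 (-4.15 ± 0.27) and Mbnl3 (-3.90 ± 0.86). In Cyp51 and Asz1 1 clone lay apart from the other 4, and so in Rps6ka6. In total 517 genes were higher and 608 lower, 263 and 270 by at least 2-fold.

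Respiratory chain genes were lower in cloned blastocysts, with 20 of 79 falling and 2 rising, or 37 and 2 adjusted over the list alone (camera adjusted p = 5.65e-08, and adjusted p = 0.218 with an estimated correlation). Members were the ATP synthase genes Atp5o (-0.73 ± 0.07) and Atp5e (-0.74 ± 0.07) and the complex genes Uqcr10 (-2.07 ± 0.21) and Sdhb (-0.64 ± 0.07). Of 48 ribosomal protein genes 16 fell, or 24 with 1 rise adjusted over the list alone (camera adjusted p = 3.78e-07, and adjusted p = 0.335 with an estimated correlation), with Rpl37a at -0.69 ± 0.06, Rps6 at -0.78 ± 0.07 and Rps15 at -1.11 ± 0.11. Proteasome genes had 6 falls of 42, among them Psmb6 (-0.60 ± 0.10) and Psma5 (-0.83 ± 0.14), or 18 adjusted over the list alone (camera adjusted p = 3.5e-05, and adjusted p = 0.696 with an estimated correlation). Of 23 mitosis genes 8 fell and 1 rose, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.004, and adjusted p = 0.431 with an estimated correlation), with Espl1 at -0.96 ± 0.13 and Bub1b at -0.90 ± 0.13. Nucleolar ribosome biogenesis factors had 6 falls, with fibrillarin (Fbl, -0.58 ± 0.06) and Nolc1 (-1.16 ± 0.14), and a rise of Bysl (0.94 ± 0.09), or 8 falls and 1 rise adjusted over the list alone (camera adjusted p = 0.00419, and adjusted p = 0.431 with an estimated correlation). The 3′/5′ difference was 0.815 higher on the clone arrays (exact p = 0.0357, adjusted 0.214), and with it as a covariate 8 genes passed. The proteasome call ended with that covariate, where the mean of the list went from -0.32 to -0.0615 (adjusted p = 0.677). In all, 6 of the 10 list calls at this stage were kept with it.

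Genes with H3K27me3-type imprinting were higher in cloned blastocysts, where 5 of 14 rose and 1 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.00166, and adjusted p = 0.218 with an estimated correlation). Gab1 (1.45 ± 0.13), the amino acid transporter gene Slc38a4 (1.94 ± 0.18), Mbnl2 (1.40 ± 0.19) and Enc1 (1.98 ± 0.27) had the smallest p. Primitive endoderm genes shifted up with Sparc (2.50 ± 0.42) and Gata6 (0.73 ± 0.14) rising, or 3 with 1 fall adjusted over the list alone (camera adjusted p = 0.00318, and adjusted p = 0.64 with an estimated correlation). Of 20 p53 and cell death genes Sesn1 (1.10 ± 0.17) rose, or 6 adjusted over the list alone (camera adjusted p = 0.000163, and adjusted p = 0.418 with an estimated correlation). Cdkn1a had 1.97 ± 0.52 and did not pass. Heat shock genes shifted up with 3 of 25 rising, Hspa1a (0.55 ± 0.09), Hspa1b (3.09 ± 0.54) and Hspe1 (0.52 ± 0.11), and Hsp90b1 (-0.94 ± 0.10) falling, or 5 and 1 adjusted over the list alone. Their camera adjusted p was 0.0373, with adjusted p = 0.335 with an estimated correlation, 0.0875 with arrays centred on their medians and 0.105 after quantile normalization. X-linked genes shifted down with 68 of 617 lower and 2 higher, or 86 and 3 adjusted over the list alone (camera adjusted p = 3.78e-07, and adjusted p = 0.418 with an estimated correlation), and their mean was -0.441 with a median of -0.0511. The hybridisation controls differed by -0.186 (exact p = 0.214), and with them as a covariate 425 genes passed.

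Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460373 to 103483233), had differences between clones and IVF embryos of -0.41 ± 0.37, 2.77 ± 1.02, 2.81 ± 1.95, 3.36 ± 1.87, 4.58 ± 0.92 and 2.41 ± 1.64 from the 1-cell stage to the blastocyst, and passed the threshold at no stage (adjusted p = 0.125 at the morula stage). No embryo was assigned a sex. From the 4-cell stage on, Xist was -5.68 to -0.45 in IVF embryos with Eif2s3y above 0 and 0.42 to 3.43 in the others. Clones had 0 to 5.31 (3.50 to 4.65 in morulae), above all of the former, so the mixed IVF groups limit the test. The X-linked offset was -0.187 ± 0.056 (SD) in cloned and 0.165 ± 0.233 (SD) in IVF morulae, a difference of -0.352 (exact p = 0.0357, adjusted 0.107). In blastocysts it was -0.307 ± 0.124 (SD) and 0.139 ± 0.057 (SD), a difference of -0.447 (exact p = 0.0357, adjusted 0.107). At the other 4 stages the exact p lay between 0.214 and 0.679. Among the other genes followed throughout, Nanog, Cdx2, Dppa3, Dnmt1, Dnmt3b and Sox9 passed at no stage. Gata6 passed only in blastocysts, Sox2 only at the 8-cell stage and Pou5f1 only at the 4- and 8-cell stages.

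**Figure D2:**
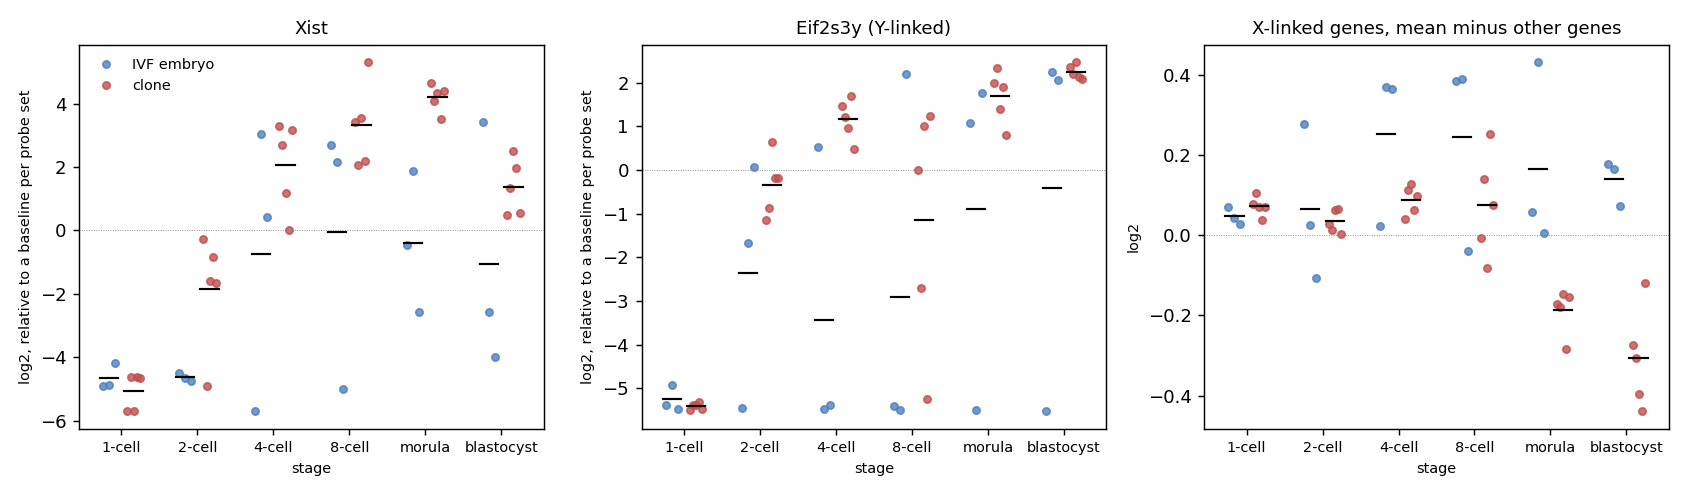
Log2 value of Xist and the X-linked offset (mean of 617 X-linked genes minus mean of the other genes, log2) in each embryo by stage, IVF in blue and clones in red, with bars for group means. All cloned morulae and blastocysts lay below all IVF embryos of their stage in the offset, by at least 0.152 in morulae and 0.193 in blastocysts.

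**Figure D3:**
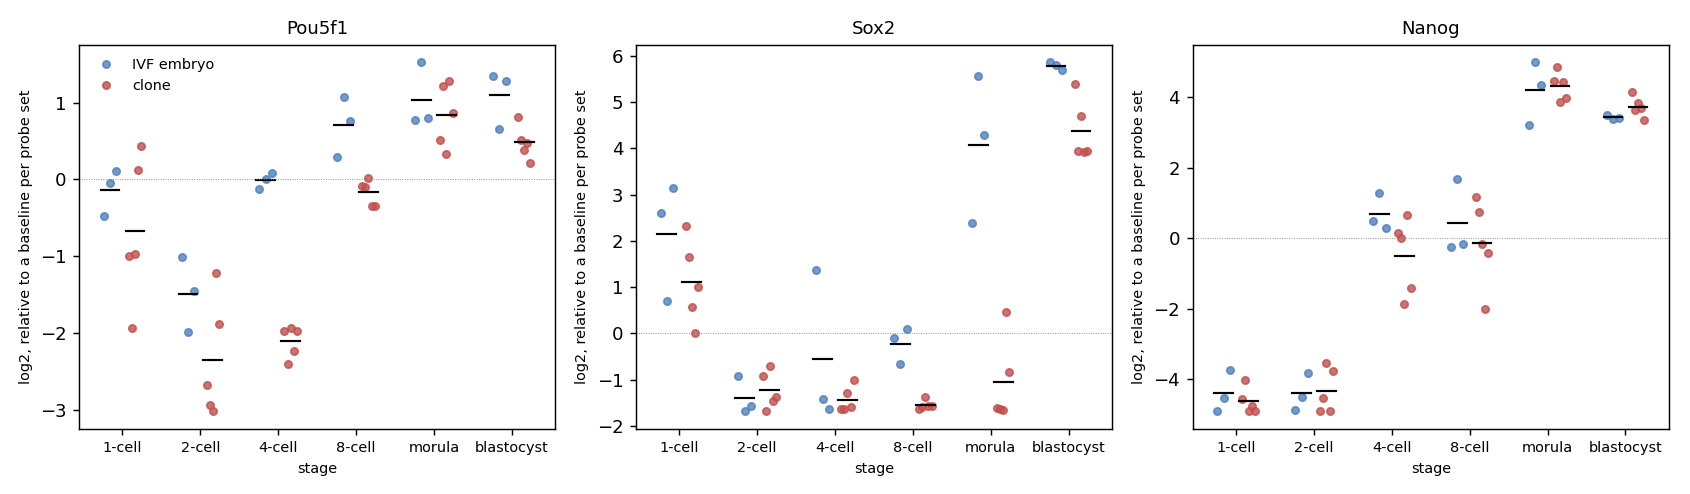
Log2 values of pluripotency genes in each embryo by stage, IVF in blue and clones in red, with bars for group means. Pou5f1 was lower in all 5 clones at the 4-cell stage (-2.09 ± 0.12), and Sox2 in morulae had means of -1.06 in clones and 4.08 in IVF embryos.

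Genes lower in clones recurred from the 2-cell to the 8-cell stage. Of 339 genes lower at the 2-cell stage and 328 lower at the 4-cell stage 61 were shared, where 6.11 would be by independence, and 132 were shared between the 4-cell and 8-cell stages, where 14.7 would be. Across genes, which are not independent replicates, the differences correlated with r = 0.373 from the 2-cell to the 4-cell stage and 0.594 from the 4-cell to the 8-cell stage. The 1-cell stage shared 13 lower genes with the 2-cell and 11 with the 4-cell stage, where 9.47 and 9.16 would be by independence (r = -0.0243 and -0.00371). Mageb16 was lower at 5 of 6 stages, and Fmr1nb, Cdk16, Uxt, D1Pas1, Krt28 and Rnf126 at 4. Of the 7 genes lower at 4 or more stages 4 were X-linked. Trim28 was higher at the 1-cell stage and lower at the 2-, 4- and 8-cell stages. The hybridisation controls on the clone arrays differed from those on IVF arrays by -0.98 at the 1-cell stage. They differed by 1.24, 1.26 and 0.826 at the 2-, 4- and 8-cell stages. Their part in the shared lower genes and in the turn of Trim28 was not tested.

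In IVF embryos, the step from oocyte to 1-cell embryo raised Plxna4, a semaphorin receptor gene, by 8.90 ± 0.54 and lowered Mos, the kinase gene that holds the oocyte in metaphase, by -8.77 ± 0.16 (adjusted p = 4.52e-09 and 1.03e-14). Other rises were in Arg2 (8.16 ± 1.21), the carbonic anhydrase gene Car9 (7.93 ± 0.51), Dedd (7.74 ± 0.44) and Usp17la (7.74 ± 1.18), and other falls in Slmap (-8.84 ± 0.35), Alg10b (-8.71 ± 0.61), Tbc1d14 (-8.66 ± 0.57) and the nuclear envelope gene Lbr (-8.24 ± 0.40). With another probe set Tbc1d14 rose by 3.67. In all 2596 genes rose and 2969 fell. Of 25 heat shock and stress genes 12 rose and 2 fell, or 13 and 2 adjusted over the list alone, among them Hsp90aa1 (4.82 ± 0.14) and Hsph1 (5.20 ± 0.29), a shift that held with an estimated correlation (camera adjusted p = 0.000992, and adjusted p = 0.0294 with an estimated correlation). Zygotic activation and 2-cell genes shifted up with 7 of 20 rising, or 8 adjusted over the list alone, such as Dppa2 by 6.99 ± 0.33 (camera adjusted p = 0.00902, and adjusted p = 0.0814 with an estimated correlation).

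From the 1-cell to the 2-cell stage in IVF embryos 3121 genes rose and 3411 fell. Among the largest rises were those of the selenoprotein gene Selenos (12.08 ± 0.21), the vitamin B6 kinase gene Pdxk (11.92 ± 0.36), Zfp622 (10.76 ± 0.54), Timd2 (10.58 ± 0.18) and the protease gene Ctsc (10.50 ± 0.51), which stood at -0.01 with another probe set. Large falls were found in Olfr976 (-8.15 ± 0.84), the phospholipase gene Plce1 (-7.96 ± 0.35), Gpr1 (-7.78 ± 0.87), Tshz1 (-7.75 ± 0.75) and the oocyte poly(A)-binding gene Pabpn1l (-7.71 ± 0.54). Ribosomal proteins rose in 42 of 48 genes and fell in 1, with Rpsa at 6.85 ± 0.14 (camera adjusted p = 1.04e-22, and adjusted p = 0.0353 with an estimated correlation). Nucleolar ribosome biogenesis factors rose in 26 of 30 and fell in 1, with Nop2 at 7.53 ± 0.27 (camera adjusted p = 3.68e-15, and adjusted p = 0.0493 with an estimated correlation). Of 20 zygotic activation and 2-cell genes 13 rose and 2 fell, or 15 and 2 adjusted over the list alone, with Pramel6 at 9.77 ± 0.35 (camera adjusted p = 1.1e-06, and adjusted p = 0.0096 with an estimated correlation). Maternal factors fell in 22 of 26, with Nobox at -4.51 ± 0.31 (camera adjusted p = 4.53e-08, and adjusted p = 0.113 with an estimated correlation).

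At the next step, from 2 to 4 cells, 1911 genes rose and 2420 fell in IVF embryos. Large rises were those of the pantetheinase gene Vnn1 (7.12 ± 0.90), the Nodal co-receptor gene Tdgf1 (7.10 ± 0.59), the claudin gene Cldn7 (6.93 ± 0.45), Smpdl3a (6.63 ± 0.63) and Ago4 (6.55 ± 0.36). Large falls were those of Nlrp4e (-6.65 ± 0.91), the matrix protease gene Mmp2 (-6.50 ± 0.22), Mapre2 (-6.31 ± 1.46), Tbx4 (-6.19 ± 0.36) and Bnc2 (-6.06 ± 0.55). Nanog rose by 5.09 ± 0.54 and Gata6 by 3.88 ± 0.82. From 4 to 8 cells 223 genes rose and 138 fell. Rises were found in Fam241a (6.06 ± 0.92), the cholesterol transfer gene Stard4 (5.27 ± 0.72), Cited2 (5.19 ± 0.75), hexokinase 2 (Hk2, 5.04 ± 0.60) and Gsto1 (4.56 ± 0.98). Falls were those of Jade2 (-3.72 ± 0.56), Ralgps2 (-3.63 ± 0.42), the X-linked Slc25a53 (-3.56 ± 0.75), Prkar2b (-3.18 ± 0.54) and Ampd3 (-3.16 ± 0.41). That count was 664 without the 4-cell IVF embryo of replicate 2 and 224 without that of replicate 3. Trophectoderm genes shifted up, with Gata3 (2.92 ± 0.40), Krt8 (3.39 ± 0.49) and Krt18 (3.16 ± 0.53) rising of 23, or 5 adjusted over the list alone (camera adjusted p = 1.44e-06, and adjusted p = 0.0359 with an estimated correlation).

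Between the 8-cell stage and the morula 1292 genes rose and 1845 fell in IVF embryos. The stress transcription factor gene Xbp1 rose by 8.66 ± 0.82, the endocytic receptor gene Lrp2 by 8.35 ± 0.34, Enpep by 7.54 ± 1.26, the glucose transporter gene Slc2a1 by 7.54 ± 0.54 and Akr1b8 by 7.08 ± 1.07. Khdc1b (-7.94 ± 0.43), Exoc3l2 (-7.91 ± 0.35), Pramel25 (-6.97 ± 0.24), Enpp3 (-6.41 ± 1.10) and the oocyte gene Oog3 (-6.35 ± 0.57) fell. Sox2 rose by 4.29 ± 0.82 and the trophectoderm regulator gene Cdx2 by 4.83 ± 0.88. Zygotic activation and 2-cell genes fell in 7 of 20 and rose in 1, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.00133, and adjusted p = 0.039 with an estimated correlation). Heat shock genes rose in 9 of 25, or 10 with 2 falls adjusted over the list alone (camera adjusted p = 0.0038, and adjusted p = 0.039 with an estimated correlation). From morula to blastocyst 2289 genes rose and 1833 fell, and 2324 and 1202 with each array centred on its median. Adh1 (10.19 ± 0.08), galectin 1 (Lgals1, 10.09 ± 0.29), the peptide transporter gene Slc15a2 (8.93 ± 0.53), Tfap2a (8.19 ± 0.60) and Efemp1 (8.00 ± 0.32) rose. Obox6 (-8.31 ± 0.27), Tnfsf13b (-6.86 ± 0.59), Tlcd4 (-6.82 ± 0.85), Ube2u (-6.62 ± 0.72) and Bex6 (-6.43 ± 0.68) fell. Trophectoderm genes rose in 16 of 23, with Gata2 at 4.26 ± 0.16 (camera adjusted p = 6.34e-11, and adjusted p = 0.0096 with an estimated correlation). Primitive endoderm genes rose in 7 of 18, with Sox17 at 6.86 ± 0.46 (camera adjusted p = 0.000149, and adjusted p = 0.0216 with an estimated correlation). Of the 144 tests of lists over the IVF transitions 51 passed, 9 of them with an estimated correlation.

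In clones, 3036 genes rose and 4469 fell from the 1-cell to the 2-cell stage. Rises were found in Pdxk (12.12 ± 0.35), Zfp622 (11.90 ± 0.17) and Selenos (11.21 ± 0.20), which also rose in IVF embryos, and falls in the X-linked translation factor gene Gspt2 (-7.68 ± 0.58), the oocyte gene Nlrp9b (-7.39 ± 0.12) and Plxna4 (-7.37 ± 0.29). Ribosomal proteins rose in 39 of 48 genes and fell in 1, or 41 and 2 adjusted over the list alone (camera adjusted p = 4.61e-27, and adjusted p = 0.00675 with an estimated correlation). Nucleolar factors rose in 24 of 30 and fell in 2 (camera adjusted p = 7.64e-14, and adjusted p = 0.0213 with an estimated correlation), the same counts as adjusted over the list alone. Zygotic activation and 2-cell genes rose in 14 of 20 and fell in 2 (camera adjusted p = 1.25e-07, and adjusted p = 0.0171 with an estimated correlation). Maternal factors fell in 24 of 26 (camera adjusted p = 7.84e-10, and adjusted p = 0.0231 with an estimated correlation). From 2 to 4 cells 2752 genes rose and 2682 fell, with Vnn1 (8.52 ± 0.70), the X-linked creatine transporter gene Slc6a8 (7.05 ± 0.48) and Tomm70a (6.77 ± 0.36) rising and Bmp5 (-7.85 ± 0.36), Gli3 (-7.63 ± 0.94) and Slco3a1 (-7.32 ± 0.36) falling. Xist rose by 3.21 ± 0.73 from the 1-cell to the 2-cell stage and by 3.91 ± 0.73 from the 2-cell to the 4-cell stage in clones. Dnmt3b rose by 1.00 ± 0.36 from 2 to 4 cells (adjusted p = 0.036) and stood at -0.22 with another probe set (adjusted p = 0.692).

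From 4 to 8 cells 424 genes rose and 758 fell in clones. They included Col4a1 (5.50 ± 0.67), Niban2 (4.88 ± 0.46) and Grtp1 (4.85 ± 0.42) rising and Klhl8 (-4.86 ± 0.42), Tgds (-4.13 ± 0.45) and the X-linked copper transporter gene Atp7a (-3.83 ± 0.59) falling. Pou5f1 rose by 1.94 ± 0.34. Into the morula 1785 rose and 1385 fell, with Lrp2 (7.07 ± 0.50), the natriuretic peptide gene Nppb (6.84 ± 0.73) and Tbx20 (6.80 ± 0.19) rising and Exoc3l2 (-6.83 ± 0.26), Tacr3 (-5.73 ± 0.63) and Fgf1 (-5.43 ± 0.73) falling. Trophectoderm genes rose in 8 of 23, or 11 adjusted over the list alone, with Cdx2 at 6.47 ± 0.32 (camera adjusted p = 5.26e-07, and adjusted p = 0.00675 with an estimated correlation). Into the blastocyst 3077 rose and 3203 fell, and 3118 and 1521 with each array centred on its median. Slc15a2 (10.15 ± 0.44), Lgals1 (9.91 ± 0.58) and the actin bundling gene Lcp1 (9.24 ± 0.60) rose, and Nppb (-7.55 ± 0.73), the X-linked gene Mid1 (-6.89 ± 0.45) and Stmn3 (-6.76 ± 0.41) fell. Sox2 rose by 5.43 ± 0.39. Xist fell by 2.83 ± 0.73 at that step (adjusted p = 0.00404) and stood at 0.65 with another probe set (adjusted p = 0.647). Trophectoderm genes rose in 17 of 23 and fell in 1 (camera adjusted p = 4.08e-10, and adjusted p = 0.00104 with an estimated correlation). Primitive endoderm genes rose in 12 of 18, with 1 fall added adjusted over the list alone (camera adjusted p = 1.15e-06, and adjusted p = 0.0314 with an estimated correlation).

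Clones shared most of the changes of IVF embryos from the 1-cell to the 2-cell stage, where 2309 of 3121 IVF rises and 2836 of 3411 IVF falls also passed in clones (521 and 838 by independence), and the changes correlated across genes with r = 0.866. From the 4-cell to the 8-cell stage 30 of 223 IVF rises and 53 of 138 IVF falls also passed in clones (5.2 and 5.75 by independence), with r = 0.316 across genes. The changes themselves differed between clones and IVF embryos in 2038 genes from the 1-cell to the 2-cell stage (721 more positive and 1317 more negative in clones). They differed in 480 from 2 to 4 cells (264 and 216), in 239 from 4 to 8 cells (52 and 187). From morula to blastocyst the number was 295 (179 and 116), and it was 1030 from the 8-cell stage to the morula (779 and 251). From the 1-cell to the 2-cell stage the mean hybridisation controls went from 0.673 to -0.468 on the IVF arrays. On the clone arrays they went from -0.307 to 0.771, and no test of these differences took them as a covariate. At the first step Usp17la differed by 7.64 ± 1.66, Ppil3 by 6.89 ± 0.94, Rbm25 by 6.50 ± 1.42, Fmr1nb by -7.09 ± 1.04, Syt11 by -7.06 ± 0.59 and C1qtnf12 by -6.46 ± 0.99. Between 2 and 4 cells Hacd2 differed by 4.84 ± 1.07, Clptm1 by 4.76 ± 0.57 and Nrip1 by 4.71 ± 1.12. On the other side were Ndrg1 by -5.57 ± 1.08, Plp2 by -4.86 ± 1.31 and Ctss by -4.70 ± 0.23. Hacd2 stood at -0.50 with another probe set. Between 4 and 8 cells Niban2 differed by 4.67 ± 0.61 and the collagen genes Col4a1 by 4.66 ± 1.10 and Col4a2 by 3.90 ± 0.82, against Pde7a at -6.29 ± 1.03, Plekhb2 at -5.14 ± 1.11 (0.19 with another probe set) and Amotl2 at -4.80 ± 0.79. From the 8-cell stage to the morula the differences were 8.61 ± 0.83 in Prmt2, 6.93 ± 1.26 in Mid1, 6.77 ± 0.80 in Tgds, -5.80 ± 1.24 in Fbxl17, -5.72 ± 1.21 in Fam122b and -5.56 ± 0.87 in Etl4. For Sox2 the change in clones minus that in IVF embryos was -3.80 ± 0.81 at this step (adjusted p = 0.00266) and 3.72 ± 0.81 from morula to blastocyst (adjusted p = 0.00596). At the last step Ankrd33b (6.45 ± 1.29), App (6.0 ± 1.35) and H2-K1 (5.95 ± 0.73) differed upward and Mid1 (-6.46 ± 1.26), Ly6e (-6.37 ± 1.04) and Plau (-5.55 ± 0.66) downward. For the counts of 4 to 8 cells and of 8 cells to morula, at least 5% of other splits of the arrays gave as many genes.

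**Figure D4:**
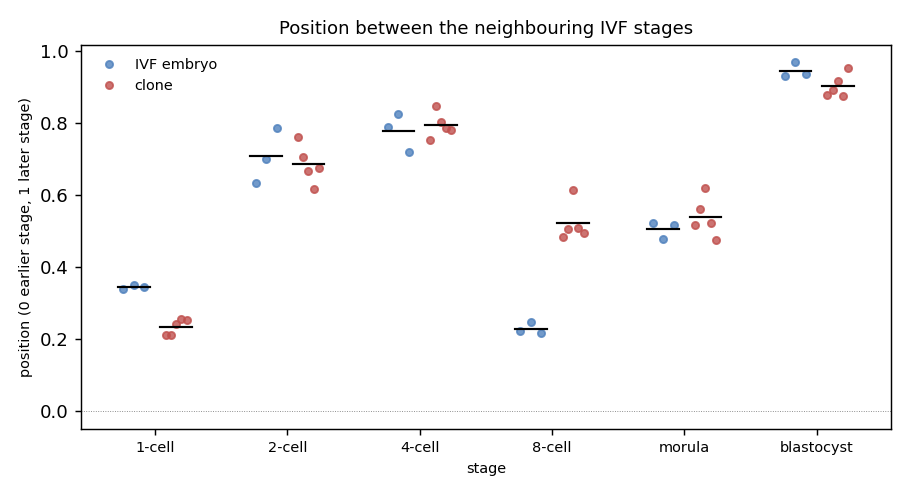
Position of each embryo on the line from the IVF stage before (0) to the IVF stage after (1), with no unit, IVF in blue and clones in red, with bars for group means. Clones at the 8-cell stage lay at 0.522 and IVF embryos at 0.229, and at the 1-cell stage clones lay at 0.235 and IVF embryos at 0.345.

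Clones at the 1-cell stage lay earlier on the line between oocytes and 2-cell IVF embryos than IVF embryos did, by -0.11 (exact p = 0.0357, adjusted 0.107). At the 8-cell stage clones lay later on the line between 4-cell embryos and morulae, by 0.293 (exact p = 0.0357, adjusted 0.107). The differences at the 2-cell and 4-cell stages, in morulae and in blastocysts were -0.0221, 0.0161, 0.0321 and -0.0423 (exact p between 0.143 and 0.679). The spread between single embryos was 0.648 in clones and 0.583 in IVF embryos at the 4-cell stage (log2, approximate permutation p = 0.0357, adjusted 0.214). At the other stages that p lay between 0.143 and 0.821. The largest spread of clones was 0.672 at the 8-cell stage and the smallest 0.354 in blastocysts.

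Several gene lists shifted at no stage between clones and IVF embryos. Trophectoderm genes had camera adjusted p between 0.138 and 0.995 over the 6 stages, epithelial junction and cavitation genes between 0.138 and 0.995, glycolysis genes between 0.0732 and 0.995, DNA replication genes between 0.107 and 0.997, and imprinted genes between 0.0981 and 0.995. Single members of these lists passed all the same. Among them, the glycolysis genes Ldha (2.99 ± 0.50), Pdk1 (2.03 ± 0.35) and Tpi1 (0.88 ± 0.17) rose and Pgk1 (-3.74 ± 0.70) fell in blastocysts. At the 8-cell stage the trophectoderm gene Hand1 fell (-4.94 ± 0.46). Markers of Sertoli cells, the donor type, had camera adjusted p between 0.176 and 0.885. Of 26 members Rhox5 rose in morulae and Aard in blastocysts (2.38 ± 0.43, adjusted p = 0.0276), while Gata4 (-4.27 ± 0.53, adjusted p = 0.00997) and Tsx (-1.55 ± 0.28, adjusted p = 0.0315) fell at the 8-cell stage. Markers of other testis somatic cells lay between 0.305 and 0.982, with 0 of 18 members past the threshold at any stage. The Xist region with the Magea and Xlr families lay between 0.276 and 0.997. The 3′/5′ difference had an exact p between 0.107 and 0.893 at the 5 stages before the blastocyst, and the hybridisation controls differed by 0.315 in morulae (exact p = 0.25).

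**Figure D5:**
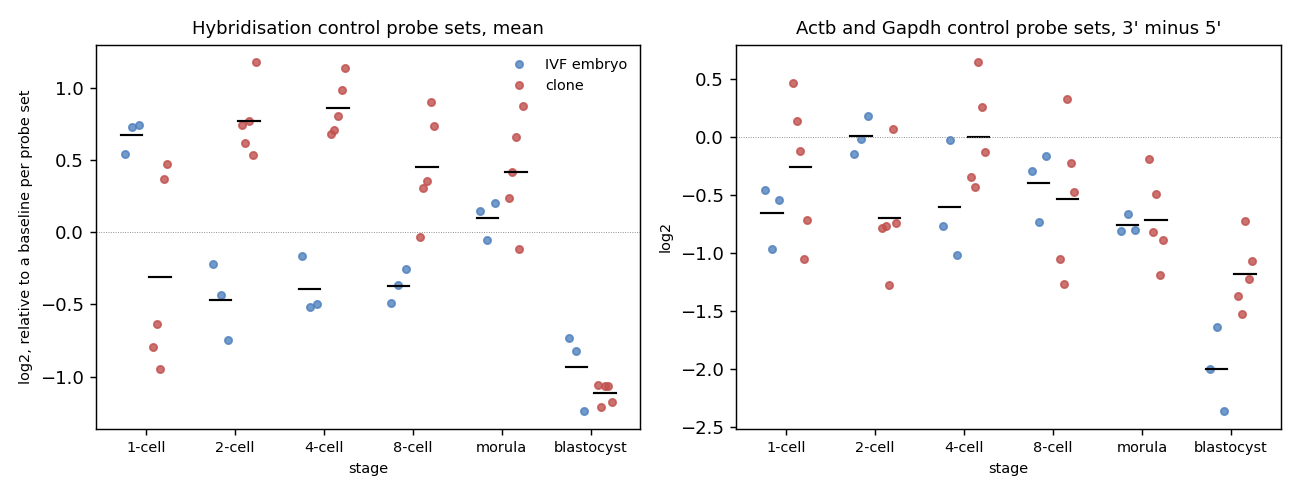
Mean of the bacterial hybridisation controls and the 3′/5′ difference of Actb and Gapdh (log2) on each array by stage, IVF in blue and clones in red, with bars for group means. The hybridisation controls of all clones lay above those of all IVF embryos at the 2-, 4- and 8-cell stages, by 1.24, 1.26 and 0.826 on average.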

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

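The tests on the hybridisation controls by stage and on X-linked genes, with Eif2s3y or the hybridisation controls as a covariate, were chosen only after the results were seen.

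Lower genes outnumbered higher ones in clones at the 2-cell (339 and 92), 4-cell (328 and 84) and 8-cell stages (813 and 391), and the counts were 164 and 127, 179 and 118, and 524 and 486 after quantile normalization, which sets the mean difference to 0 by construction. Poorer cDNA length in the clones was not decided. The size of the falls was taken in genes called on these same arrays. The called lower genes had means of -1.9, -1.87 and -2.23 without and -1.92, -1.86 and -2.25 with the 3′/5′ difference as a covariate. With it 83.7%, 84% and 73.1% of the called genes were lower, of fewer calls (8 higher and 41 lower, 17 and 89, and 294 and 799). At the 8-cell stage clones lay 0.293 later on the line between IVF stages (exact p = 0.0357, adjusted 0.107), where a lag predicts an earlier place. From that stage to the morula 1845 genes fell and 1292 rose in IVF embryos, so a broad fall could itself move clones later. A lag was thus not decided there. A lag could not be decided at the 2-cell and 4-cell stages, with differences in position of -0.022 and 0.016 (exact p = 0.679 and 0.643). Less labelled cRNA on the clone arrays stayed open at the 2-cell and 4-cell stages. It was tested on all genes lower in clones by over 1 log2, called or not (1948, 1848 and 2867 at the 2-, 4- and 8-cell stages). Arrays with higher hybridisation controls had lower values of those genes within groups (r = -0.586, permutation p = 0.0344, 24 arrays). The implied fall reached 95% limits of -0.845 and -0.858 at the 2-cell and 4-cell stages. Mean falls in embryos not used to pick the genes were -0.95 (-1.32 to -0.565 over 120 splits) and -0.961 (-1.27 to -0.687). At the 8-cell stage the limit of -0.563 stayed short of the fall of -1.34 in such embryos (-1.84 to -0.961). The slope was pooled over these stages, however. With the controls as a covariate 15 genes passed at the 8-cell stage and 1 of the 8 list calls was kept. Less labelled cRNA as the whole cause was thus not decided there. A part in the fall, and a biological difference at each stage, stayed open and untested.

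X-linked genes were lower in cloned morulae and blastocysts, with mean differences of -0.38 and -0.441 and medians of 0.00574 and -0.0511 (adjusted p = 0.845 and 0.418 with an estimated correlation). IVF embryos of both sexes were argued against as the explanation in blastocysts, where the lowest IVF embryo lay 0.193 above the highest clone in the X-linked offset, the IVF blastocysts with Eif2s3y at 2.24 and 2.06 had offsets of 0.166 and 0.074, and the list kept an adjusted p of 7.02e-06 with Eif2s3y as a covariate. In morulae the gap was 0.152, and the IVF morulae with Eif2s3y at 1.07 and 1.77 had offsets of 0.0576 and 0.00602 against -0.284 to -0.146 in clones. The sex of the IVF embryos stayed undecided there, since the IVF morula with Eif2s3y at -5.49 had the highest offset, 0.432, and with that covariate the mean went from -0.38 to -0.237 (adjusted p = 0.00173 and 0.217). Strain differences at the probes, with B6CBF1 donor nuclei and B6D2F1 IVF embryos, and a biological difference stayed open and untested.

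Ribosomal, respiratory chain and proteasome genes were lower in cloned blastocysts, with mean differences of -0.286, -0.268 and -0.32 (adjusted p = 0.335, 0.218 and 0.696 with an estimated correlation). A difference in cDNA length was not decided, since the 3′/5′ difference of all clones lay above that of all IVF embryos. With it as a covariate the means were -0.288, -0.309 and -0.0615 (adjusted p = 2.29e-05, 3.77e-10 and 0.677). A lag of clones was argued against for all of these lists, whose means rose by 0.385, 1.23 and 0.616 from IVF morula to blastocyst, because the position of clones implied falls of only -0.0163, -0.0521 and -0.0261. A biological difference stayed open as a hypothesis, found and tested on the same data.

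The counts of genes were set against other splits of the same arrays into groups of the same sizes. For clones and IVF embryos 1 of 56 splits, the real one, gave as many genes at each stage, with 1148, 431, 412, 1204, 30 and 1125 genes from the 1-cell stage to the blastocyst and at most 178, 9, 8, 48, 5 and 7 in any other split. IVF transitions have 10 splits, too few to decide, of which 1 gave as many. The real counts were 5565, 6532, 4331, 361, 3137 and 4122, and the highest others 19, 17, 41, 50, 13 and 17. In clone transitions 1 of 100 splits gave as many, with real counts of 7505, 5434, 1182, 3170 and 6280 and highest others of 4562, 2296, 402, 902 and 1050. For the differences of transitions 1, 3, 12, 7 and 3 of 100 splits gave as many as the real 2038, 480, 239, 1030 and 295 genes. The highest others there were 1081, 1436, 3566, 2106 and 396, so single splits called several times the real count from 2 to 4 and from 4 to 8 cells. The cause of these high counts was not tested. For the counts of 239 and 1030 genes an arbitrary grouping of the arrays thus stayed open.

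The hybridisation controls were not a covariate in any test of a difference of transitions. The change of a gene between stages differed between clones and IVF embryos, by the test of the difference itself, in the following genes. From the 1-cell to the 2-cell stage these were Usp17la (7.64, adjusted p = 0.00119), Ppil3 (6.89, 1.28e-06), Rbm25 (6.50, 0.00133), Fmr1nb (-7.09, 5.03e-06), Syt11 (-7.06, 1.97e-11) and C1qtnf12 (-6.46, 1.01e-05), of 2038 genes. From 2 to 4 cells they were Hacd2 (4.84, adjusted p = 0.00663), Clptm1 (4.76, 9.45e-07), Nrip1 (4.71, 0.0118), Ndrg1 (-5.57, 0.00184), Plp2 (-4.86, 0.0315) and Ctss (-4.70, 2.79e-18), of 480. From 4 to 8 cells they were Niban2 (4.67, adjusted p = 1.44e-05), Col4a1 (4.66, 0.0213), Col4a2 (3.90, 0.00778), Pde7a (-6.29, 0.000559), Plekhb2 (-5.14, 0.00888) and Amotl2 (-4.80, 0.000559), of 239. Between the 8-cell stage and the morula they were Prmt2 (8.61, adjusted p = 4.69e-09), Mid1 (6.93, 0.000402), Tgds (6.77, 2.53e-07), Fbxl17 (-5.80, 0.00266), Fam122b (-5.72, 0.00245), Etl4 (-5.56, 3.9e-05) and Sox2 (-3.80, 0.00266), of 1030. Between morula and blastocyst they were Ankrd33b (6.45, adjusted p = 0.00233), App (6.0, 0.00801), H2-K1 (5.95, 5.81e-07), Mid1 (-6.46, 0.00173), Ly6e (-6.37, 0.00012), Plau (-5.55, 3.2e-07) and Sox2 (3.72, 0.00596), of 295.

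In 29 of 186 groups of 5 clones 1 embryo lay far from the other 4 by Dixon's test, where chance gives about 1 in 20, or 9.3. At the 1-cell stage these were replicate 3 in Med20 (-0.99, others 0.33 to 0.72), replicate 1 in Dcdc2c (2.01, others -0.01 to 0.00) and replicate 4 in Cdx2 (2.23, others -0.29 to -0.08). At the 2-cell stage they were replicate 5 in Gpr50 (0.66), replicate 4 in Tial1 (-3.24, others -4.06 to -3.88) and replicate 1 in the spread (0.665, others 0.613 to 0.623). At the 4-cell stage replicate 2 lay apart in Mageb16 (-2.04, others -4.49 to -3.82), Fmr1nb (-1.94, others -3.41 to -3.39) and Fzd4 (0.67, others -0.03 to 0.03), replicate 5 in Fez1 (6.39, others 4.85 to 5.27), replicate 1 in Cdx2 (0.00, others -0.28 to -0.24) and replicate 3 in Sox9 (1.47). At the 8-cell stage replicate 4 lay apart in Etl4 (-2.19, others -0.10 to 0.43), Cthrc1 (5.02, others -0.16 to 0.38) and Klhl8 (-2.92, others -5.58 to -5.55). Further 8-cell clones apart were replicate 2 in Borcs6 (0.91), replicate 3 in Sox2 (-1.38) and in position (0.614, others 0.484 to 0.509), and replicate 5 in Cdx2 (0.27). Among morulae replicate 4 lay apart in Fos (2.33, others 2.81 to 2.94), H2-K1 (2.16), Rps6ka6 (-3.75, others -5.04 to -4.87) and the X-linked offset (-0.284, others -0.178 to -0.146). Other morulae apart were replicate 1 in Gosr2 (2.37, others 3.00 to 3.05), replicate 2 in Cthrc1 (1.33) and replicate 5 in Dnmt3b (-1.63). Among blastocysts replicate 1 lay apart in Cyp51 (3.81, others 2.94 to 3.09) and Asz1 (-2.76, others -2.28 to -2.27), and replicate 3 in Rps6ka6 (-3.15, others -5.08 to -4.93).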

How the results depend on the processing

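The probe set with the highest mean, the filter on the lowest 30% by SD, and Eif2s3y or the hybridisation controls as a covariate were tests chosen only after results were seen. The planned filter on the lowest 30% of genes by mean was not run, since means of centred values hold no level. Of 7364 values of alternatives for 436 results on named genes, 6478 kept direction and side of the threshold, 635 no longer passed, 33 newly passed, 11 turned sign past the threshold in one setting and 207 turned sign past it in neither. The cause was not tested for any change below. Signal over background was not judged, and the number of embryos limits every count.

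The count of genes at the 1-cell stage (1148) was 758 with the highest-mean probe set, 37 with the replicate block, 1955 with all 51 arrays in one fit, 619 with Eif2s3y and 521 with the hybridisation controls as a covariate. At the 2-cell stage (431) it was 686 with the SD filter, 0 with the block, 1915 in one fit, 49 with the 3′/5′ covariate, 228 with Eif2s3y and 0 with the hybridisation controls. The 4-cell count (412) was 0 with the block, 1549 in one fit, 694 with array weights, 106 with the 3′/5′ covariate and 0 with the hybridisation controls. The 8-cell count (1204) was 0 with the block, 3787 in one fit, 2252 with array weights, 528 with Eif2s3y and 15 with the hybridisation controls. The morula count (30) was 120 with the SD filter, 0 with the block, 608 in one fit, 211 with array weights, 14 with the 3′/5′ covariate and 7 with the hybridisation controls. The blastocyst count (1125) was 533 at 2-fold, 633 with the highest-mean probe set, 0 with the block, 535 in one fit, 8 with the 3′/5′ covariate, 539 with Eif2s3y and 425 with the hybridisation controls. Where limma called 0 with the block, from the 2-cell stage on, 1942, 2024, 3420, 1730 and 2872 genes had an unadjusted p under 0.05, and with the hybridisation controls 890 and 1701 did at the 2-cell and 4-cell stages. Clones with a number that no IVF embryo had add nothing to a comparison with the block. That fit so rested on fewer arrays and had less power, and its counts do not show an effect of batch. For clones the count from 4 to 8 cells (1182) was 759 with the highest-mean probe set, and that from morula to blastocyst (6280) was 3534 at 2-fold and 4186 with the SD filter.

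Leaving out 1 embryo gave between 604 and 970 genes at the 1-cell stage, 218 and 311 at the 2-cell, 233 and 387 at the 4-cell and 479 and 1028 at the 8-cell stage, 6 and 65 in morulae and 548 and 887 in blastocysts. A shift over 1.5-fold followed the loss of clones 1 (722) and 2 (761) and IVF embryos 1 (699), 2 (604) and 3 (713) at the 1-cell stage, and of clones 2 (218), 3 (228), 4 (263) and 5 (223) and IVF embryos 2 (238) and 3 (283) at the 2-cell stage. It followed that of clone 4 (269) and IVF embryos 1 (247) and 2 (233) at the 4-cell stage, and of clone 3 (658) and IVF embryos 1 (479), 2 (483) and 3 (565) at the 8-cell stage. In morulae these were clones 1 (11), 3 (6), 4 (65) and 5 (8) and IVF embryos 1 (59), 2 (53) and 3 (46), and in blastocysts clones 2 (583), 3 (744) and 4 (667) and IVF embryos 1 (577), 2 (613) and 3 (548). The IVF count from 4 to 8 cells (361) was 664 without 4-cell embryo 2 and 224 without 4-cell embryo 3.

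With another probe set the sign turned for Snx6 (1.23) at the 1-cell stage, Nolc1 (0.41) at the 2-cell stage, Socs2 (0.0551) at the 8-cell stage and Gosr2 (-0.33) in morulae. It also turned for Tbc1d14 (3.67) and Ctsc (-0.00774) in IVF transitions, Dnmt3b (-0.22) and Xist (0.65) in clone transitions, and Hacd2 (-0.50) and Plekhb2 (0.19) in differences of transitions. Plin2 at the 4-cell stage turned to -0.78 with the hybridisation controls.

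Gene lists past the threshold from the 1-cell stage to the blastocyst (1, 5, 8, 8, 6 and 10) were 0 at every stage with an estimated correlation, where 1, 3, 5, 2, 0 and 4 had an unadjusted p under 0.05. Of the 1, 5, 8, 8, 6 and 10 lists 1, 2, 0, 1, 3 and 9 passed in the same direction with the hybridisation controls as a covariate, 1, 5, 5, 7, 5 and 6 with the 3′/5′ difference, 1, 3, 6, 7, 2 and 9 with Eif2s3y and 0, 4, 5, 7, 6 and 9 with the block. At the 1-cell stage there were 2 with fry, 3 with the mean of probe sets, 2 with the highest-mean probe set and 1 to 5 without 1 embryo. Leaving out 1 embryo gave 3 to 6 at the 2-cell stage and 2 to 9 in morulae. The SD filter gave 5 at the 4-cell and 4 at the 8-cell stage, and fry gave 5 at the 8-cell stage and 0 in morulae, where limma's fry had 5 at an unadjusted p under 0.05. Over IVF transitions (51) there were 9 with an estimated correlation and 80 with fry, and over clone transitions (38) 9 and 58. The spread of clones minus that of IVF embryos lay, without 1 embryo, between -0.0045 and 0.0197 at the 1-cell stage, -0.0443 and 0.0434 at the 2-cell stage, 0.0291 and 0.0825 at the 4-cell stage, 0.0572 and 0.13 at the 8-cell stage, 0.0229 and 0.111 in morulae and -0.0394 and 0.0279 in blastocysts. The 3′/5′ difference was -0.431 with Actb alone and 1.64 with Gapdh alone (exact p = 0.0357) at the 4-cell stage. With Gapdh alone it was 0.403 at the 8-cell stage and -0.0799 in morulae, and with Actb alone 0.517 in blastocysts (exact p = 0.0714).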

Other observations

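Single embryos differed in the Y-linked gene Eif2s3y, which encodes a translation initiation factor subunit. Of the clones, made from male nuclei, the 8-cell embryo of replicate 4 had -5.25 and the 4 others of that stage values between -2.70 and 1.23, while the 3 oocytes lay between -5.42 and -5.37. Its X-linked offset was 0.253 against -0.0812 to 0.14 in those others, and its label was in doubt. Its position in development, 0.509, lay within the range of the clones of that stage (0.484 to 0.614). The IVF embryos of that stage lay between 0.218 and 0.246. The 5 cloned blastocysts lay between 2.09 and 2.47. Among IVF blastocysts replicates 1, 2 and 3 had Eif2s3y at -5.52, 2.24 and 2.06 and Xist at 3.43, -2.57 and -3.99. All 5 cloned 1-cell embryos had Eif2s3y between -5.50 and -5.32, and the 5 cloned 2-cell embryos between -1.15 and 0.63.

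In clones 10 genes were higher and 67 lower at 3 or more stages. From the 4-cell to the 8-cell stage 23 higher genes were shared, where 1.81 would be by independence. Rpap3, which encodes a partner of the R2TP chaperone, was higher at the 1-cell stage (1.15) and lower at the 2-cell (-0.94), 4-cell (-0.696) and 8-cell stages (-1.09), as Trim28 was (3.17, -1.81, -1.32 and -1.68). At these stages the hybridisation controls on the clone arrays differed by -0.98, 1.24, 1.26 and 0.826 from those on IVF arrays. Their part in this pattern was not tested.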
